A study of Mus musculus with 2 samples.

How the data were processed

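Single-cell suspensions of lymph node immune cells were captured with a 10x Chromium 3′ v3.1 kit per the labels' protocols, with 1 library per genotype and both libraries from mice of the C57BL/6 strain. The deposited values are UMI counts per gene and barcode for 32285 genes, whole numbers without normalization. The count files name Cell Ranger 6.0.2 per the file headers, whereas the submitters' processing notes list Cell Ranger 5.0.0, Seurat 4.0.3 and the build mm10; the version that made the counts is therefore uncertain. Every barcode held at least 500 UMIs. Groups were taken from the genotype labels. Gene positions come from GENCODE M21 on GRCm38, where 32158 of the 32285 gene identifiers (99.6%) were found.

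Cells with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept; 306 WT and 437 CKO barcodes exceeded the mitochondrial limit. Doublets were scored with the Scrublet method in Scanpy 1.11.5, and the highest-scoring cells were left out at a rate of 0.8% per 1000 barcodes of a library, 1304 in WT and 1513 in CKO. Both libraries were clustered together without integration, on log counts per 10000, 2000 variable genes without Rpa1, receptor variable segments, mitochondrial and sex-linked genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9). T cells were clustered again with the same settings. Clusters were named from marker genes fixed before the data were examined, together with the gene lists, the comparisons, the naming rule of genes and the alternatives marked as planned.

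Several naming thresholds were set after seeing the data. A cluster stayed unnamed where markers of another class were as many as its own among its 10 leading genes. It also stayed unnamed where Cd3e and Cd79a were each found in at least 25% of its cells, whether or not in the same cells. A T cluster stayed unnamed where Cd79a was found in at least 25% of its cells. The other T clusters were called by relative levels of Cd4, Cd8a and Cd8b1, Foxp3 and Trdc with a threshold of 0.3. Markers of an interferon response or of cycling were then made to speak for no class, a change made after B cell clusters led by interferon-stimulated genes had lost their name under some alternatives. Clusters 15, 16, 17 and 18 and T cluster 13 were left out of all classes in this way, together 327 WT cells (2.93%) and 391 CKO cells (3.31%). Cluster 15 was led by histone and cycling genes such as Pclaf, Ccna2 and Rrm2, and cluster 16 by Ctla4 and Foxp3 beside B cell markers. Cluster 17 was led by major histocompatibility class II genes at a low UMI count, and cluster 18 by Il1rl1 and Il4. T cluster 10, led by Maf and Ctla4, had a relative Foxp3 level of 0.294, close to the threshold, and was kept as CD4-like. Cluster 24, led by Rag1 and named B cell-like, held 20 cells, all from the CKO library. Clusters led by interferon-stimulated genes were not compared in size, since those genes differed between the libraries.

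Counts were summed per class and library and scaled to CPM by the total. With 1 library per group no test was made. Shares have exact binomial intervals, CPM exact Poisson intervals and ratios exact conditional binomial intervals, all at 95% and for counting error only. Genes with at least 50 CPM in a library were ranked by the CKO over WT ratio, and the 10 highest and 10 lowest in T cell-like and B cell-like cells (5 and 5 in CD4-like and CD8-like cells) whose interval excluded 1 were named. Receptor and immunoglobulin variable, diversity and joining segments, mitochondrial and sex-linked genes, predicted genes and genes at least 10 times as high, in both libraries, in another class of at least 100 cells (free RNA) were left out. From each list the 2 highest and 2 lowest members with at least 20 CPM could be named, as could Rpa1, Rpa2, Rpa3, marker genes and the genes of the UMI shares. The genes named in T clusters 0, 2, 3 and 4 and T clusters 1 and 5 follow the same ranking, on clusters chosen after seeing the data. Gene lists were summarized by the median log2 ratio of members with a mean of at least 5 CPM (20 CPM in NK cell-like cells, γδ-like T cells and the regulatory cluster), set beside 10000 random lists matched on mean CPM in 20 bins. For shares of cells with a UMI, every cell was thinned to 2000 UMIs.

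The steps were tested on simulated data. For a comparison shaped like that of T cell-like cells, counts were drawn from the WT means and both totals with 200 changed genes; of 2660 genes at the floor, 94.7% had an interval that held the true ratio, and the direction was recovered for 100% of genes changed 1.5-fold and 100% of those changed 2-fold. For B cell-like cells, with 2839 genes, these figures were 95.4%, 100% and 100%. Of 200 lists of unchanged genes, 5.0% in the T cell-like and 1.5% in the B cell-like simulation fell outside the central 95% of random lists. The simulation holds no variation between animals, so it says nothing of how far 2 libraries of 1 genotype would differ.

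Summed totals were 52934010 UMIs in WT and 22677106 in CKO for T cell-like cells and 12396799 and 32388976 for B cell-like cells, so small classes are the least precise. Alternatives changed 1 choice at a time: the filters, the doublet step, the Leiden resolution, clustering each library on its own, the scaling (TMM factors of edgeR 4.0.16 in R 4.3.3, or totals without ribosomal protein and mitochondrial genes), a mean over cells, the CPM floors and the thinning. Added after seeing the data were equal cluster make-up, subsets of T clusters, no cell filter, the own threshold of Scrublet, co-receptor gating, T cluster 10 counted as regulatory, and T cell-like cells without T cluster 10. TMM factors moved the log2 ratios of all genes by -0.07 in T cell-like, -0.04 in CD4-like, -0.08 in CD8-like and -0.02 in B cell-like cells. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.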

Results

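Immune cells from lymph nodes of wild-type mice (WT) and of mice with a conditional knockout of Rpa1 (CKO), both on a C57BL/6 background, were profiled by droplet-based single-cell RNA sequencing of transcript 3′ ends with unique molecular identifiers (UMIs). Each genotype was represented by 1 library. The WT library held 12769 barcodes and 84813609 UMIs, with a median of 5984 UMIs and 1952 genes per barcode. The CKO library held 13754 barcodes and 76200586 UMIs, with a median of 4549 UMIs and 1725 genes. After filtering, 11169 WT cells (87.5%) and 11804 CKO cells (85.8%) remained. No difference between the genotypes could be set against variation between animals, so no test was made, and all intervals are exact 95% intervals that cover counting error only.

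The first question was how far Rpa1 transcripts differed between the libraries. Rpa1 encodes the largest subunit of replication protein A, which coats single-stranded DNA during replication and repair (ENSMUSG00000000751, build GRCm38, chromosome 11, 75298166 to 75348324, minus strand). Over all kept cells it stood at 40.5 CPM (counts scaled to the total of the class; interval 39.0 to 42.0) in WT and 32.8 CPM (31.4 to 34.3) in CKO, a CKO over WT ratio of 0.811 (0.765 to 0.858). In T cell-like cells the level was 40.1 CPM in WT (2124 UMIs) and 25.003 CPM in CKO (567 UMIs), a ratio of 0.623 (0.567 to 0.684). In CD4-like T cells it was 44.5 and 22.8 CPM, a ratio of 0.513 (0.457 to 0.576), and in the Foxp3-led regulatory cluster the ratio was 0.603 (0.386 to 0.934).

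The lower Rpa1 level was not shared by all lymphocytes. In B cell-like cells Rpa1 stood at 39.3 CPM in WT and 35.4 CPM in CKO, a ratio of 0.901 (0.809 to 1.003), and in NK cell-like cells the ratio was 1.24 (0.758 to 2.12). The γδ-like T cells, with 5 Rpa1 UMIs in WT and 47 in CKO, gave a ratio of 1.11 (0.444 to 3.58). In CD8-like T cells it stood at 33.9 and 29.8 CPM, a ratio of 0.878 (0.730 to 1.05) whose interval overlapped that of B cell-like cells. In T clusters 1 and 5 alone, without T clusters 7 and 14, which were led by granzyme genes, the log2 ratio was -0.45. This lay within the counting interval of the whole CD8-like class. Most CKO cells of T cluster 7 held a transcript of the δ receptor chain, as given below. Rpa2 and Rpa3, the genes of the other replication protein A subunits, had T cell-like ratios of 0.960 (0.854 to 1.08) and 1.05 (0.965 to 1.14). Rpa2 stood at 1.41 (1.17 to 1.70) in CD8-like T cells, and Rpa3 at 0.844 (0.758 to 0.941) in B cell-like cells. The labels name neither the deleted exons nor the cells in which the gene was deleted, and 3′ tags can lie outside a deleted part, so these levels check neither the genotype nor the extent of deletion.

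**Figure D1:**
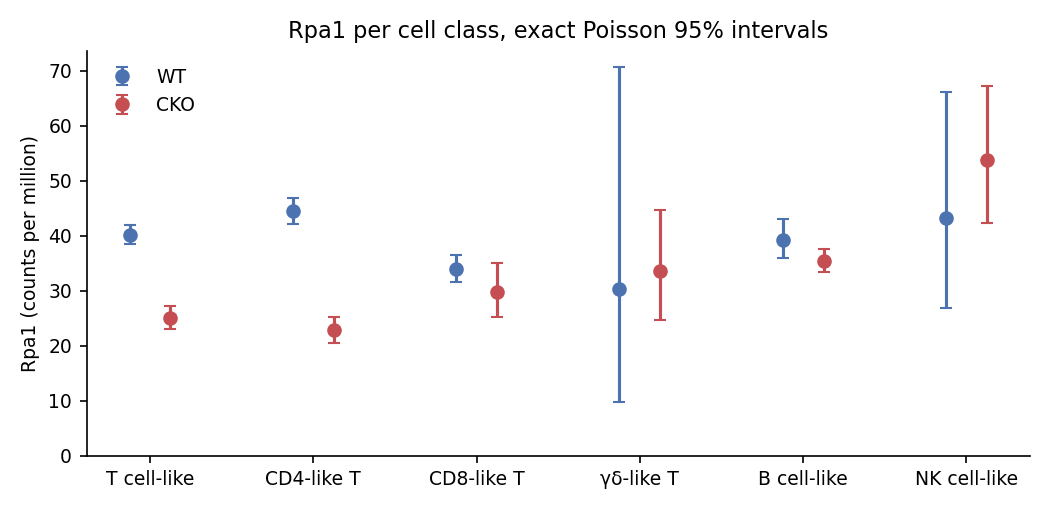
Rpa1 level in CPM (vertical axis) by cell class (horizontal axis) in the WT and CKO libraries, 1 library each. Points are summed counts per class and bars exact Poisson 95% intervals; CD4-like T cells stood at 44.5 CPM in WT and 22.8 CPM in CKO.

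The make-up of the lymph node cell suspension differed widely between the libraries. T cell-like cells were 70.7% of kept cells in WT (7893 of 11169; 69.8 to 71.5%) and 31.4% in CKO (3707 of 11804; 30.6 to 32.3%). B cell-like cells were 24.6% (23.8 to 25.4%) and 61.9% (61.1 to 62.8%), so that the number of T cell-like cells per B cell-like cell was 2.87 in WT and 0.507 in CKO. NK cell-like cells were 0.725% (0.576 to 0.901%) in WT and 2.01% (1.76 to 2.28%) in CKO. Monocyte or macrophage-like cells were 0.340% and 0.305%, conventional dendritic cell-like cells 0.260% and 0.347%, and plasma cell-like cells 0.233% and 0.364%, with overlapping intervals. Clusters left unnamed held 2.93% of WT and 3.31% of CKO cells. Shares of captured cells give no cell numbers per lymph node, and the number of nodes or mice behind each library is not given in the sources used here.

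Among T cell-like cells, CD8-like cells were under-represented and γδ-like cells over-represented in CKO. CD4-like cells, the regulatory cluster included, were 63.4% of T cell-like cells in WT (62.4 to 64.5%) and 76.5% in CKO (75.1 to 77.9%). CD8-like cells were 36.1% (35.1 to 37.2%) and 17.1% (15.9 to 18.4%), which gave 1.76 CD4-like cells per CD8-like cell in WT and 4.47 in CKO. The γδ-like cluster, led by the receptor constant genes Trdc, Tcrg-C1, Tcrg-C2 and Tcrg-C4, held 0.418% of T cell-like cells in WT (33 cells; 0.288 to 0.587%) and 6.34% in CKO (235 cells; 5.58 to 7.17%). This difference of 5.92 points was 10.3 with mitochondrial UMIs at most 20% and 13.3 with each library clustered on its own. The CD8-like and γδ-like shares count T cluster 7 as CD8-like, though most of its CKO cells held a Trdc UMI, as given below. In CKO they may therefore overstate CD8-like and understate γδ-like cells, and the number of CD4-like cells per CD8-like cell depends on the same naming. Of cells thinned to 2000 UMIs that held transcripts of 1 co-receptor only, those with Cd8a or Cd8b1 made up 63.6% in WT (62.2 to 65.0%) and 42.4% in CKO (40.1 to 44.8%). Without thinning these shares were 49.7% and 32.3%.

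The CD8-like class held different cells in the 2 libraries. T cluster 1, led by Cd8b1 and Lcn4, held most of it in WT (57.7%), whereas T cluster 7, led by Gzmm and Klrc2, was its largest single part in CKO (42.0%, against 13.3% in WT), ahead of T clusters 1 (28.7%) and 5 (25.5%). Of the cells of T cluster 7, 231 of 267 in CKO (86.5%; 81.8 to 90.4%) but 27 of 379 in WT (7.12%; 4.75 to 10.2%) had a UMI of Trdc, the constant gene of the δ receptor chain (chromosome 14, 54142851 to 54148868). Among all CD8-like cells thinned to 2000 UMIs, with 1 WT and 2 CKO cells left out as shallower, Trdc was found in 1.37% in WT and 30.6% in CKO, and without thinning in 2.84% and 41.3%. In B cell-like cells, which should lack it, the thinned share was 0 of 2730 cells in WT, with an upper limit of 0.135%, and 0.166% in CKO (unthinned 0.0364% and 0.410%). In NK cell-like cells, however, it was 13.75% in WT and 12.8% in CKO (unthinned 29.6% and 32.5%). A Trdc UMI was thus not confined to T cell-like cells. Unthinned, it was still more frequent in CKO cells of T cluster 7 (86.5%) than in CKO NK cell-like cells (32.5%). Median depths there were 8499 and 5372 UMIs. The naming rule thus placed cells with δ chain transcripts in the CD8-like class, and most CKO cells of T cluster 7 may be γδ T cells. Without T cluster 7, the CD8-like share was 22.2 points lower in CKO than in WT, against 19.0 points lower with it. That setting also leaves out the cells of T cluster 7 without a Trdc UMI, which were most of its WT cells.

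**Figure D2:**
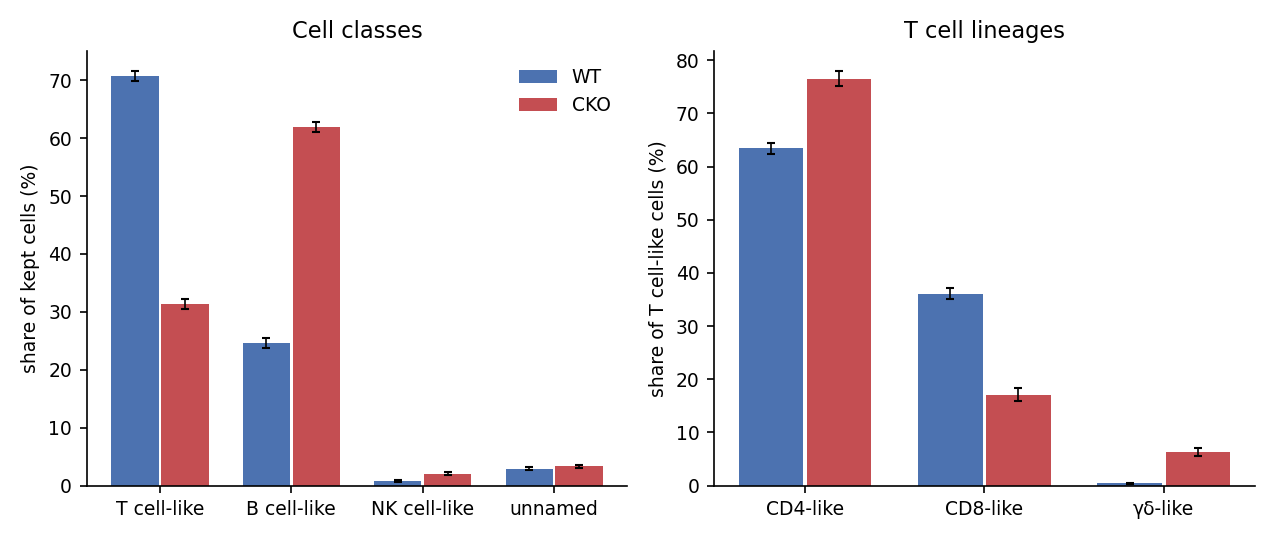
Left, shares of kept cells by class; right, shares of T cell-like cells by lineage (vertical axes in percent) in the WT and CKO libraries, 1 library each. Bars are shares with exact binomial 95% intervals; T cell-like cells were 70.7% in WT and 31.4% in CKO.

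T cell-like cells of the CKO library carried more transcripts of interferon-stimulated genes and fewer of Il7r, which encodes the interleukin-7 receptor α chain (chromosome 15, 9505788 to 9530176), a survival receptor of naive T cells, and of Dapl1 (chromosome 2, 59484653 to 59505020). Il7r stood at 379 CPM in WT and 173 CPM in CKO, a ratio of 0.457 (0.441 to 0.473), and Dapl1 at 372 and 160 CPM, a ratio of 0.431 (0.416 to 0.447). The antiviral membrane protein gene Ifitm3 (chromosome 7, 141009586 to 141010770) stood at 18.2 and 101 CPM, a ratio of 5.55 (5.15 to 5.99). Isg15, which encodes a ubiquitin-like interferon-induced protein (chromosome 4, 156199424 to 156200818), stood at 353 and 684 CPM, a ratio of 1.94 (1.90 to 1.98). Of 2716 ranked genes with at least 50 CPM in a library, 7 were at least 2-fold higher and 3 at least 2-fold lower in CKO.

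The other genes ranked highest in CKO T cell-like cells were Trdc (ratio 12.0), the calcium-binding protein gene S100a6 (4.57), the MYC antagonist gene Mxd1 (2.25), the interferon-induced GTPase gene Iigp1 (2.18), the transcription factor gene Sox4 (2.09), the antiviral enzyme gene Rsad2 (2.06), Ly6c1 (1.97) and the ISG15 protease gene Usp18 (1.92). Those ranked lowest were Cd8a (0.495), Cd8b1 (0.540), the mTORC1 inhibitor gene Ddit4 (0.570), Tent5a (0.602), the ribosomal protein gene copy Rps27rt (0.612), the glucocorticoid-induced Tsc22d3 (0.629), Izumo1r (0.635) and Dnajc15 (0.661). With the cluster make-up held equal between the libraries, an alternative chosen after seeing the data, the log2 ratios of Cd8a and Cd8b1 turned from -1.01 and -0.89 to 0.02 and 0.03. The genes at least 2-fold apart numbered 10 with the clusters as they fell, 3 with their make-up held equal and 30 with a floor of 20 CPM. Rps27rt closely resembles another gene copy, so its counts are uncertain.

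Within CD4-like T cells, where T cluster 0 held the largest part in WT and T cluster 3 in CKO, Il7r stood at 386 and 143 CPM (ratio 0.371, 0.355 to 0.388), and Ifitm3 at 23.3 and 120 CPM (5.14, 4.72 to 5.61). Rsad2 (2.19), Isg15 (2.12), Mxd1 (2.07) and Pmepa1 (44.3 and 86.7 CPM), a gene induced by TGF-β, were also higher in CKO. Dapl1 (0.440), Ddit4 (0.497), Izumo1r (0.537) and Ibtk (0.587) were lower. Of 2738 ranked genes, 4 were at least 2-fold higher and 3 at least 2-fold lower in CKO. This count of 7 became 3 with cluster make-up held equal, 15 with totals without ribosomal protein and mitochondrial genes, and 21 with a floor of 20 CPM. In T clusters 0, 2, 3 and 4 alone, chosen after seeing the data, the Il7r ratio was 0.377 (0.358 to 0.397) and that of Ddit4 0.468 (0.416 to 0.524). Sox4 was higher there, at 28.4 CPM in WT and 58.7 CPM in CKO (2.07, 1.85 to 2.32), as were Pmepa1 (2.14) and Cd8b1 (2.49; 20.8 and 52.0 CPM).

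Within CD8-like T cells the genes with the highest ratios in CKO were those of the γδ receptor chains, Tcrg-C1 (47.3), Tcrg-C4 (36.4), Trdc (29.5) and Tcrg-C2 (29.3), and S100a4 (20.99), a calcium-binding protein gene of effector and memory cells, whose log2 ratio turned from 4.39 to -1.04 with each library clustered on its own. Those with the lowest ratios were Dapl1 (0.386), Lcn4 (0.474), the interleukin-6 receptor gene Il6ra (0.524), the sodium pump gene Atp1b1 (0.540) and Rps27rt (0.560). Of 2704 ranked genes, 27 were at least 2-fold higher and 2 at least 2-fold lower. This count of 29 became 4 with cluster make-up held equal. These 4, S100a6, Trdc, Ly6a and Lgals1, were all higher in CKO. Trdc is among them, and that setting does not equalize the kinds of cells inside T cluster 7. The count became 71 with a floor of 20 CPM, and 11 in T clusters 1 and 5 alone, where 4 were higher and 7 lower. In those clusters Il7r stood at 358 and 144 CPM (0.401, 0.359 to 0.447). Iigp1 (2.24), the Helios gene Ikzf2 (2.18), Ccr9 (2.05), Ift80 (2.01) and Pmepa1 (1.93) were higher there in CKO. The immediate early gene Fos (0.371), Klrd1 (0.421), Tent5a (0.462) and Lcn4 (0.463) were lower.

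**Figure D3:**
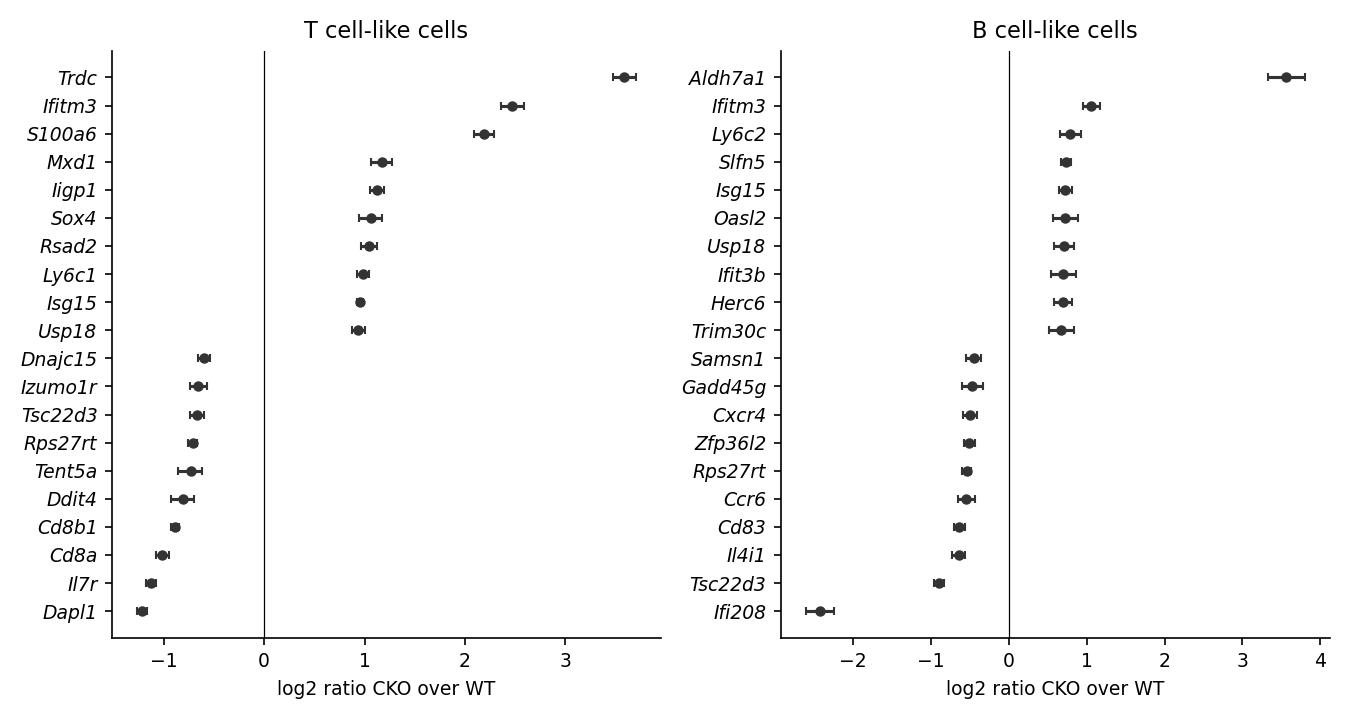
Log2 ratio CKO over WT (horizontal axis) of the genes ranked highest and lowest in T cell-like cells (left) and B cell-like cells (right), 1 library per genotype. Points are ratios of summed CPM and bars exact conditional binomial 95% intervals; Ifitm3 had a ratio of 5.55 in T cell-like and 2.09 in B cell-like cells.

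Of all gene lists, that of interferon-stimulated genes had the highest median log2 ratio in B cell-like cells. In T cell-like cells its median lay below those of immunoglobulin constant genes (0.88, 5 members measured, all at least 10 times as high in another class) and regulatory T cell genes (0.59), and in CD4-like T cells below those of immunoglobulin constant (0.92) and B cell identity genes (0.86, 3 members measured). In CD8-like T cells the interferon list lay below those of activation and effector (1.25), helper T cell subset (0.92), immunoglobulin constant (0.75) and regulatory T cell genes (0.53). In T cell-like cells 48 of its 49 measured members had counting intervals on the CKO side and 1, Ifi208, on the WT side; the median log2 ratio was 0.54, above all 10000 random lists matched on expression, whose central range was 0.04 to 0.12. The median was 0.54 in CD4-like, 0.41 in CD8-like and 0.43 in B cell-like cells. Rsad2 (2.06) and Iigp1 (2.18) led in T cell-like cells, whereas Ifi214 (1.09) differed little. Several T cell and B cell clusters were led by interferon-stimulated genes, and holding the cluster make-up equal gave medians of 0.15 in T cell-like, 0.07 in CD4-like, 0.36 in CD8-like and 0.14 in B cell-like cells. The median was 0.30 in CD4-like T clusters 0, 2, 3 and 4 alone and 0.44 in CD8-like T clusters 1 and 5 alone. Interferon-stimulated genes were not left out of the clustering. Holding clusters led by them equal, or leaving out T cluster 6, led by Ifitm3 and Rsad2, therefore removes part of the difference by construction. These values cannot tell cell make-up from a difference in the level of these genes within cells. Percentiles among random lists describe these libraries only.

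Genes of naive and effector T cells gave values that depended on which clusters entered. Naive and quiescent T cell genes had a median of 0.02 in T cell-like cells, with 11 members on the CKO side, Slfn2 among them (1.21), and 8 on the WT side, led by Dapl1 and Il7r. In CD8-like T cells the median was -0.19, below all random lists, but 0.00 in T clusters 1 and 5. Activation and effector genes had a median of 1.25 in CD8-like T cells, with S100a4 (20.99) and S100a6 (20.8) leading, but -0.13 in T clusters 1 and 5 and -0.75 with each library clustered on its own, where S100a4 was lower in CKO as well. In CD4-like T cells the median was -0.20, with Il2ra (1.64) higher and Icos (0.512), which encodes a co-stimulatory receptor, lower, against 0.03 in T clusters 0, 2, 3 and 4. In CD4-like T cells 13 of the 29 measured members were at least 10 times as high in another class, and the median was -0.06 with members at a mean of at least 20 CPM. Transcripts of B cells also differed within T cell-like cells: Igkc stood at 26.9 CPM in WT and 49.4 CPM in CKO, against 9307 and 9406 CPM in B cell-like cells.

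The lists of regulatory and follicular helper T cell genes had medians of opposite sign, each with members on both sides. Foxp3, the lineage factor of regulatory T cells, stood at 11.7 CPM in WT and 26.5 CPM in CKO T cell-like cells (2.27, 2.02 to 2.54). After thinning to 2000 UMIs, with 32 WT and 17 CKO cells left out as shallower, a Foxp3 UMI was found in 1.76% (1.48 to 2.07%) and 4.28% (3.65 to 4.99%) of T cell-like cells, against 0.0733% and 0.0415% of B cell-like cells. The unthinned shares were 3.53% and 7.31% in T cell-like and 0.218% and 0.0957% in B cell-like cells; median depths were 6289 and 5743 UMIs in T cell-like and 4024 and 3880 in B cell-like cells. The regulatory cluster made up 4.25% (3.71 to 4.85%) of CD4-like cells in WT and 10.4% (9.30 to 11.6%) in CKO, a difference of 6.15 points that was 0.789 points with no cells left out as doublets. It depends on the naming of T cluster 10, led by Maf and Ctla4, whose relative Foxp3 level of 0.294 lay just under the threshold of 0.3 and which held 355 WT and 41 CKO cells. Counted as regulatory, an alternative chosen after seeing the data, it gave shares of 11.3% (10.5 to 12.3%) and 11.8% (10.7 to 13.1%). The regulatory T cell list had a median of 0.59 in T cell-like cells, with 10 of 14 measured members on the CKO side and 4 on the WT side, Foxp3 and Il2ra (2.07) highest and Ctla4 (0.605) lowest. The follicular helper list, with 6 of 15 members measured, stood at -0.21, with 2 on the CKO side and 4 on the WT side, among them Maf, a transcription factor of helper T cells, at 29.1 and 8.51 CPM (0.293, 0.251 to 0.340). Without T cluster 10, also chosen after seeing the data, the regulatory and follicular helper medians were 0.98 and -0.10, and the ratio of Maf was 0.844 (0.706 to 1.005). The ratio of Ctla4 turned there to 1.23 (1.06 to 1.42), and that of Foxp3 was 3.34 (2.94 to 3.80).

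Genes of DNA replication, which replication protein A serves, had a median log2 ratio of 0.13 in T cell-like cells (percentile 97.48 of the random lists), 0.41 in CD8-like cells (percentile 100) and 0.44 in T clusters 1 and 5. Of 29 measured members in T cell-like cells, 14 had intervals on the CKO side and none on the WT side, led by the replicative helicase genes Mcm5 (1.45) and Mcm2 (1.36). Sides were counted against a ratio of 1, whereas the matched random lists themselves had a median of 0.06. A split toward CKO was not particular to this list: 47 nuclear genes of oxidative phosphorylation were on the CKO side and 3 on the WT side there, at percentile 35.45. G2 and mitosis genes, with 7 of 30 members measured, had a median of -0.09 in T cell-like cells (percentile 2.27; 3 on the CKO side, 2 on the WT side) and 0.35 in CD8-like cells. After thinning to 2000 UMIs a UMI of Top2a, a gene of dividing cells, was found in 1.59% (1.33 to 1.89%) of WT and 1.003% (0.707 to 1.38%) of CKO T cell-like cells. In CD4-like T cells it was found in 1.53% and 0.567%. The remaining T cell-like cells, CD8-like and γδ-like together, did not share this direction, as their share was not lower in CKO. The unthinned shares were 5.61% and 3.05% in T cell-like and 5.15% and 1.41% in CD4-like T cells. Cluster 15, led by histone and cycling genes such as Pclaf, Ccna2 and Rrm2, was left out of all classes. It held 116 WT and 101 CKO cells, with Cd3e in 70.5% and Cd79a in 47.5% of them. The Top2a shares and the replication and mitosis lists therefore describe T cells without that cluster, and do not give the share of dividing T cells as a whole. DNA damage signalling and repair genes had a median of 0.02 in T cell-like cells, with Msh6 (1.37) highest and Xpa (0.859) lowest. The p53 target genes had a median of 0.07 at percentile 49.99 in T cell-like cells, with Trp53inp1 (1.16) highest and Ei24 (0.896) lowest. In T clusters 1 and 5 their median was 0.25 at percentile 98.1, with 3 of 17 measured members on the CKO side and 1 on the WT side. Cytosolic ribosomal protein genes were lower in CKO in T cell-like and B cell-like cells, with 71 of 80 on the WT side in T cell-like cells (median -0.11, and -0.06 with cluster make-up held equal) and 67 of 80 in B cell-like cells (-0.08). In the regulatory cluster 3 were on the CKO side and 60 on the WT side (-0.12). By contrast, 16 and 5 were so in NK cell-like cells (0.04) and 24 and 1 in γδ-like T cells (0.08), all with a floor of 20 CPM. TMM factors move every log2 ratio in T cell-like cells, random lists included, by -0.07, which left a median of 0.06 for replication genes.

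**Figure D4:**
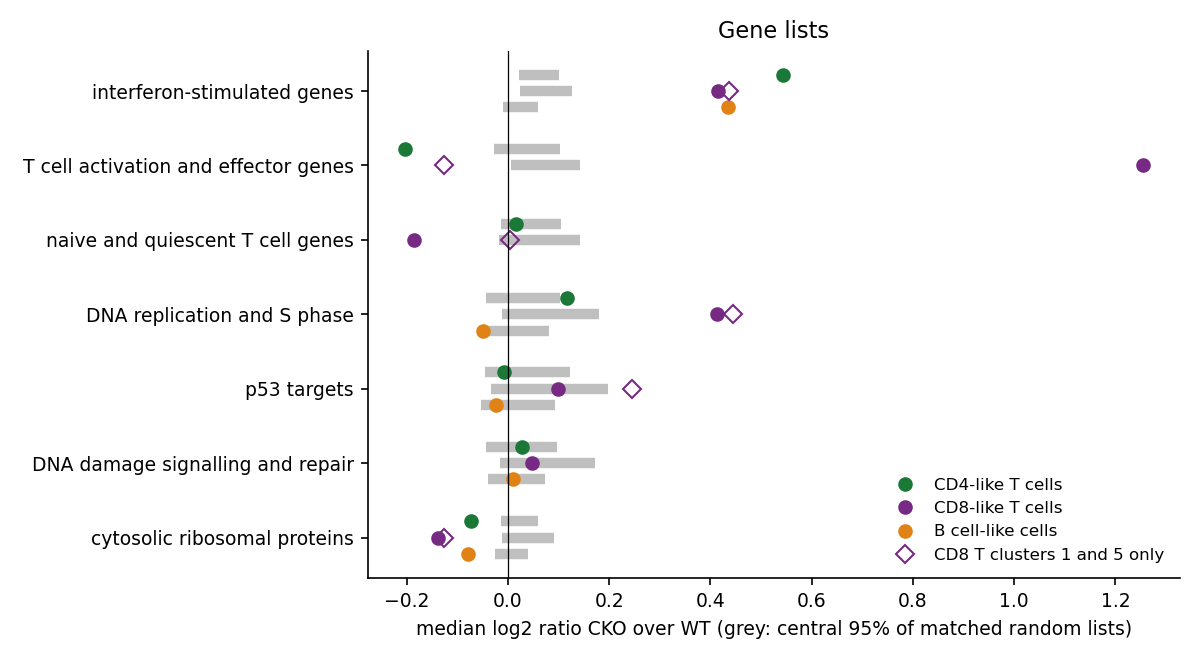
Median log2 ratio CKO over WT (horizontal axis) of 7 gene lists (vertical axis) in CD4-like T, CD8-like T and B cell-like cells, and in T clusters 1 and 5 (open diamonds), 1 library per genotype. Grey bars are the central 95% of random lists matched on expression; the median of activation and effector genes was 1.25 in CD8-like T cells and -0.13 in T clusters 1 and 5.

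B cell-like cells were compared in the same way, since the labels do not name the cells in which Rpa1 was deleted. The gene with the highest ratio was Aldh7a1, an aldehyde dehydrogenase gene of lysine breakdown (chromosome 18, 56509687 to 56572951), at 12.7 CPM in WT and 149 CPM in CKO (11.8, 10.1 to 13.9). Ifitm3 (2.09), Ly6c2 (1.73), Slfn5 (1.66), Isg15 (1.66), Oasl2 (1.66), Usp18 (1.63), Ifit3b (1.63), Herc6 (1.62) and Trim30c (1.60) followed, most of them interferon-stimulated. Ifi208, a member of the interferon-inducible p200 family (chromosome 1, 173673675 to 173698395), had the lowest ratio, at 61.5 and 11.5 CPM (0.187, 0.165 to 0.212). Tsc22d3 (0.540), the amino acid oxidase gene Il4i1 (0.643), the activation marker gene Cd83 (0.645) and the chemokine receptor genes Ccr6 (0.688) and Cxcr4 (0.711) were also lower in CKO. So were Rps27rt (0.689), Zfp36l2 (0.704), Gadd45g (0.725) and Samsn1 (0.733).

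Of 2846 ranked genes in B cell-like cells, 2 were at least 2-fold higher and 1 at least 2-fold lower in CKO, and clusters 0 and 1 held most of the class in both libraries. B cell identity genes had a median log2 ratio of 0.04, within the range of random lists (percentile 79.5). Of 21 members, 9 were on the CKO side, 1 was on the WT side and 11 had intervals that held 1, with Cr2 (1.22) highest and Ebf1 (0.977) lowest. Immediate early and dissociation genes, which cell handling also induces, had a median of 0.19, above all random lists, with 15 of 20 on the CKO side and 1 on the WT side (12 and 5 of 20 in T cell-like cells, median 0.12), Klf4 (1.58) and Dnaja1 (1.45) highest. Nuclear genes of oxidative phosphorylation had a median of -0.04, below all random lists, with 23 of 81 members on the WT side, 2 on the CKO side and 56 with intervals that held 1. All 13 mitochondrially encoded genes were on the CKO side in the same cells (median 0.08, percentile 98.9), whereas in T cell-like cells 9 of them were on the WT side and 3 on the CKO side (-0.06).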

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

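The items here were singled out by rules applied to finished values, and none was tested between the libraries.

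The list of replication genes had medians of opposite sign in B cell-like and T cells, but no clear side in B cell-like cells, where 2 of 27 measured members were on the CKO side, 2 on the WT side and 23 had intervals that held 1. The median log2 ratio of the DNA replication and S phase list was -0.05 in B cell-like cells (percentile 2.0 of random lists), 0.12 in CD4-like T cells (percentile 98.9) and 0.41 in CD8-like T cells. The B cell-like value lay -0.166 from the CD4-like and -0.461 from the CD8-like value, differences that were not tested. Mcm6, a subunit of the replicative helicase, had a ratio of 1.71 in CD8-like cells and 0.979 in CD4-like cells.

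Unnamed clusters held a larger share of cells in CKO than in WT in 3 cases. Cluster 17, led by Cst3 and major histocompatibility class II genes at a median of 1155 UMIs in CKO, held 0.771% of kept cells there and 0.412% in WT. Cluster 18, led by Il1rl1, Il4 and Il17rb, held 0.593% and 0.313%, and a Trdc UMI was found in 41.4% of its CKO and 40.0% of its WT cells. T cluster 13, led by B cell genes such as Ms4a1 and Cd79a, held 1.75% of the cells clustered as T cells in CKO and 0.328% in WT, and a Trdc UMI was found in 57.6% of its CKO cells (38 of 66) and 3.85% of its WT cells (1 of 26).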

How the results depend on the processing

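Every setting here was run on 1 library per genotype, so a value that held says nothing of variation between animals. Of the results set against other settings, the main ones kept their value in 217 cases, moved in 81 and reversed in 7, and the others kept it in 719, moved in 152 and reversed in 6. A value counted as kept within the counting interval of the reported one, or within a fixed fold of it for a gene count. Wide intervals therefore keep values more readily: the Rpa1 log2 ratio in CD8-like T cells ran from -0.452 to -0.122 and counted as kept in all 12 settings. Of 676 values of named genes, 673 kept their direction. Where a value moved, the cause was not tested. Shares are CKO minus WT in points, lists are median log2 ratios, and gene counts are genes at least 2-fold apart.

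As reported, the share differences were -39.3 (T cell-like), 37.3 (B cell-like), -19.0 (CD8-like, of T cell-like), 5.92 (γδ-like, of T cell-like) and 6.15 (regulatory, of CD4-like). Gene counts were 10 in T cell-like, 7 in CD4-like and 29 in CD8-like T cells. Interferon-stimulated genes stood at 0.54, 0.54, 0.41 and 0.43 in T cell-like, CD4-like, CD8-like and B cell-like cells, ribosomal proteins at -0.11 in T cell-like and -0.08 in B cell-like cells, S phase genes at 0.13, p53 targets at 0.07 and naive T cell genes at 0.02 in T cell-like cells. Effector genes stood at -0.20 in CD4-like and 1.25 in CD8-like T cells, and naive T cell genes at -0.19 in CD8-like T cells.

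With Leiden resolution 2.0 the T cell-like share was -40.5, B cell-like 35.4, CD8-like -22.7 and regulatory 1.80. Interferon-stimulated genes were 0.57 in T cell-like and 0.57 in CD8-like cells, and in CD8-like cells the gene count was 16, effector genes 0.39 and naive T cell genes -0.086. With Leiden resolution 0.5 the regulatory share was 1.60 and effector genes in CD4-like T cells -0.074.

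With mitochondrial UMIs at most 20% the B cell-like share was 33.8, CD8-like -23.1 and γδ-like 10.3; 1 B cell cluster was left unnamed there. Effector genes were -0.30 in CD4-like and 0.51 in CD8-like T cells, where the gene count was 13 and naive T cell genes -0.093, and ribosomal proteins in B cell-like cells -0.086. With at least 1000 UMIs per cell the regulatory share was 1 point.

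With each library clustered on its own the B cell-like share was 35.5, CD8-like -24.6, γδ-like 13.3 and regulatory 3.23. Effector genes were -0.32 in CD4-like T cells and ribosomal proteins -0.10 in B cell-like cells. In CD8-like T cells 3 values reversed: effector genes to -0.75, naive T cell genes to 0.053 and the log2 ratio of S100a4 from 4.39 to -1.04.

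With no cells left out as doublets the CD8-like share was -21.3 and regulatory 0.789, effector genes -0.06 in CD4-like and 1.36 in CD8-like T cells, and in CD8-like T cells interferon-stimulated genes 0.45 and naive T cell genes -0.29. With Scrublet's own threshold, chosen after seeing the data like the next 3 settings, the CD8-like share was -23.3 and γδ-like 9.94. With no filter on cells these were -25.1 and 10.2, and regulatory 1.30. The CD8-like share was -22.2 without T cluster 7 and -21.2 among cells with a UMI of 1 co-receptor only after thinning. With T cluster 10 counted as regulatory, also chosen after seeing the data, the regulatory share was 0.502.

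With TMM factors in T cell-like cells interferon-stimulated genes were 0.47, ribosomal proteins -0.18 and S phase genes 0.057, and p53 targets (-0.001) and naive T cell genes (-0.049) reversed. In CD8-like T cells interferon-stimulated genes were 0.33 and naive T cell genes -0.27, and in B cell-like cells ribosomal proteins -0.10. TMM factors moved all log2 ratios in T cell-like cells by -0.07, random lists included, so these 2 reversals follow from the scaling and say nothing of the lists; the same holds for the next setting, which moved them by -0.07 as well.

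With totals without ribosomal protein and mitochondrial genes in T cell-like cells interferon-stimulated genes were 0.47, ribosomal proteins -0.18 and S phase genes 0.056, and p53 targets (-0.003) and naive T cell genes (-0.05) reversed. In CD4-like T cells the gene count was 15, interferon-stimulated genes 0.50 and effector genes -0.31. In CD8-like T cells the gene count was 46, interferon-stimulated genes 0.33 and naive T cell genes -0.27, and in B cell-like cells ribosomal proteins -0.10. With a mean over cells of each cell's CPM interferon-stimulated genes were 0.58, ribosomal proteins -0.13 and S phase genes 0.10 in T cell-like cells, and effector genes 1.34 in CD8-like T cells.

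With genes with at least 20 CPM the gene counts were 30 in T cell-like, 21 in CD4-like and 71 in CD8-like T cells, and with at least 100 CPM 14 in CD8-like T cells. With list members with a mean of at least 1 CPM effector genes were -0.29 in CD4-like T cells, and with a mean of at least 20 CPM -0.062 there and 1.03 in CD8-like T cells.

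With the cluster make-up held equal, chosen after seeing the data like the 2 subsets that follow, the gene counts were 3 in T cell-like, 3 in CD4-like and 4 in CD8-like T cells. Interferon-stimulated genes were 0.15 in T cell-like, 0.069 in CD4-like, 0.36 in CD8-like and 0.14 in B cell-like cells, and ribosomal proteins -0.062 in T cell-like and -0.064 in B cell-like cells. Clusters led by interferon-stimulated genes are themselves held equal here, which removes part of the difference in those genes by construction. Effector genes were -0.004 in CD4-like and 0.41 in CD8-like T cells, and naive T cell genes -0.019 in CD8-like T cells. Cells inside a cluster are not equalized by this setting, and the share with a Trdc UMI inside T cluster 7 differed between the libraries. In T cell-like cells naive T cell genes (-0.01) and the log2 ratios of Cd8a (from -1.01 to 0.019) and Cd8b1 (from -0.89 to 0.033) reversed.

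In CD4-like T clusters 0, 2, 3 and 4 only, interferon-stimulated genes were 0.30 and effector genes reversed to 0.029. That subset leaves out T cluster 6, which was led by interferon-stimulated genes. In CD8-like T clusters 1 and 5 only, the gene count was 11, effector genes reversed to -0.13 and naive T cell genes to 0.005.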

Other observations

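Of the tests in this part, 2 were set before their results were seen (thinning of all barcodes and the count of cells with several Rpa1 UMIs); the others were chosen after.

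Apart from the comparisons above, some gene lists had medians above the central range of random lists in T cell-like cells, though the intervals of many members held 1. Apoptosis regulators had a median log2 ratio of 0.19 (percentile 99.9; 12 of 21 on the CKO side and 1 on the WT side), with the anti-apoptotic Bcl2 at 222 CPM in WT and 338 CPM in CKO (1.52, 1.48 to 1.57) and Casp8 at a ratio of 1.31. Genes of fatty acid and cholesterol metabolism had a median of 0.16 (percentile 99.9; 15 of 30 on the CKO side, 1 on the WT side), with the cholesterol exporter gene Abca1 (1.40) and the sterol synthesis gene Cyp51 (1.34) highest. In CD8-like T cells that list lay at percentile 55.0, with 21 of 26 intervals that held 1. Co-inhibitory genes had a median of 0.23 (6 of 11 on the CKO side, 1 on the WT side), with Nr4a1, a gene induced by receptor stimulation, at 20.4 and 40.7 CPM (1.997, 1.83 to 2.18). T cell receptor signalling genes (0.09, percentile 65.7) and glycolysis genes (0.02, percentile 8.63) stayed within the range of random lists in T cell-like cells, whereas glycolysis genes lay at percentile 97.8 in CD8-like T cells (0.19; 7 of 14 on the CKO side).

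Interferon-stimulated genes were also higher in the smaller CKO classes. With members at a mean of at least 20 CPM, the median log2 ratio was 0.65 in NK cell-like cells, with 27 of 45 members on the CKO side and 1 on the WT side, 0.47 in γδ-like T cells, with 23 of 49 on the CKO side, and 0.58 in the regulatory cluster, with 37 of 47 on the CKO side. Each lay above all 10000 random lists. Both libraries held Y-linked transcripts: in B cell-like cells Ddx3y stood at 89.9 CPM in WT and 89.3 CPM in CKO, and Uty at 25.9 and 23.6 CPM, whereas Eif2s3y stood at 83.01 and 18.7 CPM.

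The lower T cell-like share in CKO was set against 3 explanations. Without any cell filter the share was still -38.31 points from that in WT. All deposited barcodes were also thinned to 1000 UMIs, with 338 WT and 397 CKO barcodes left out as shallower. The share with T cell and without B cell transcripts then lay at -38.38 points. These values argue against the filters applied here and against the depth of the deposited barcodes as its cause. Every deposited barcode held at least 500 UMIs, so cell calling or filtering before deposit was not tested. An even loss over T cell clusters is also argued against, since the CKO over WT ratio of cell numbers was 50.35 times as high (34.4 to 73.7, counting error only) in T cluster 11, the γδ-like cells, as in the CD8-like T clusters 1 and 5. These clusters were chosen after the ratios were seen, and the interval does not cover that choice. The ratios of T clusters 11 (7.12) and 1 (0.111) were the highest and the lowest of all T clusters. Fewer T cells, more B cells, and a difference between the individual mice, their lymph nodes or cell preparation all stay open, since shares of captured cells from 1 library per genotype were the only measure.

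Rpa1 transcripts remained in CKO CD4-like T cells at 22.8 CPM. Free RNA could bring only 0.195 CPM, judged by Igkc, whose level there was 0.551% of that in B cell-like cells. A shift of the whole CKO library would bear on the lower level than in WT, not on the transcripts that remained. As the cause of that lower level it is argued against by the ratio of 0.9007 in B cell-like cells (0.809 to 1.003). For a mixture of cells at the WT rate and cells without Rpa1 transcripts, the reading depended on scaling by the excess seen in WT (198 cells, 172.8 expected). There were 32 CKO CD4-like cells with at least 2 Rpa1 UMIs. With the scaling, 49.8 (36 to 64) were expected for such a mixture and 28.4 for a single lower rate. Observed over expected was then 0.643 (0.445 to 0.844, cells resampled, a spread added after the count was seen) for the mixture and 1.13 (0.803 to 1.47) for the single rate. Without the scaling, which the rule set beforehand did not name, the mixture would give 43.4 (31 to 57) and the single rate 24.7. That interval holds the 32 cells seen, so by the rule set beforehand the mixture is not argued against and stays open. A mixture in which cells that lost the gene keep some transcripts stays open, and transcripts of a deleted allele that keep their 3′ end may contribute; neither was tested.

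Of the genes with at least 20 CPM in a library in both T and B cell-like cells, 2 had intervals beyond 2-fold in the same direction in both classes, Aldh7a1 (17.1 and 11.8) and Eif2s3y (0.281 and 0.225). For 100% of them the class with less held over 0.1 of the level of the other. Free RNA was not tested by this, since the floor of 20 CPM in both classes fixed the outcome. The higher levels were 149 CPM for Aldh7a1 in CKO and 83.01 CPM for Eif2s3y in WT, both in B cell-like cells. With equal cluster make-up 100% of the genes stayed 2-fold apart in both classes, which argues against cluster make-up for these genes. They formed 0 pairs within 20 Mb, as did the median random pair of genes, and with 2 genes on chromosomes 18 and Y a region from another strain cannot be told apart from other differences between the individual mice. Such a region, or a Y chromosome of another origin, may underlie them, as a hypothesis only.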
